A study of Mus musculus with 282 samples.

How the data were processed

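The data were 2 tables of gene values for 282 mouse liver libraries prepared with a QuantSeq 3' mRNA kit for forward reads, 234 libraries of 13 arms in the first and 48 tunicamycin libraries of 3 arms in the second. Reads were aligned with STAR 2.7.3a and handled with SAMtools (version not given) against mm10 (GRCm38.p6), per the submitters' processing notes. The counting program, annotation version and normalization are not given in the sources used here. The deposited values are a signal that is not whole: every value of a library, outside the exception below, was a whole multiple of a step of that library, so the authors' tables hold read counts divided by a factor per library. Multiplying back gave whole reads for 100% of values in both tables, within 0.01 read. In the first table the factors were set in separate groups of arms, so levels were rescaled before arms were compared. In the RPKO arm 192 genes lay on a second step, 0.771 to 0.782 times the main step, and 5 more left the main step in 1 or 2 libraries. These were left out of fits with that arm, which tested 12267 genes. Each table had 15907 gene symbols, and 7 had no values in the second.

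Libraries were assigned to arm, time and replicate from their labels. Every group had 3 or 4 libraries, taken as separate mice, as the labels name biological replicates. No libraries were near-copies, since the highest correlation over all pairs of libraries was 0.988 in the first table and 0.982 in the second. Depth was 0.706 to 14.3 M recovered reads in the first table and 4.85 to 10.1 M in the second. The 3 libraries under 3 M reads were night-fed BMKO ZT 6 replicate 1 (2.81 M), night-fed BMKO ZT 22 replicate 3 (2.18 M) and night-fed WT with rapamycin ZT 22 replicate 1 (0.706 M). They were kept in the tests and left out in an alternative.

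Before the data were examined the groups, comparisons, gene lists, rule for named genes and first set of alternatives were fixed, with edgeR's quasi-likelihood test as the test. Since the deposited values are scaled and not counts, limma 3.58.1 in R 4.3.3 was used instead, with a mean-variance trend, on log2 of RPM after TMM rescaling plus a pseudocount of 0.5. Fold changes are on that scale, which understates changes of genes with few reads. Genes with a mean of at least 1 RPM (reads per M reads, M being 10 to the power of 6) over the libraries of a table were tested, 12413 in the first table and 12261 in the second. The model had a mean for each arm and time and took libraries as independent. A daily mean difference weighted all times equally, a rhythm was the joint test of 24 h cosine and sine contrasts, and a rhythm difference compared these contrasts between arms. Each set of arms was fitted together (feeding arms, WT and BMKO with and without injection, liver knockouts with their control, AZD8055 arms with theirs, tunicamycin arms), and rhythmic genes of an arm were found in that arm alone. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05.

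The named genes are the targeted and core clock genes, up to 6 members of each fixed list with the smallest adjusted p in a comparison, the 8 highest and 8 lowest daily mean differences with the same sign at every time and a mean of at least 5 RPM in an arm, the 8 largest falls and rises in amplitude, and the 8 rhythmic genes of largest amplitude per arm. Unnamed gene models were passed over. Results for some genes are not reported here. From these the text takes those with a known role that are told apart from near-identical copies, and leaves out some whose call was lost under an alternative. The tests over alternatives cover the larger set. Genes given as examples of the rhythms shared by both genotypes were chosen after their values were seen.

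The 31 gene lists held 515 genes, of which 478 were in the first table and 445 were tested there. Lists were tested with camera on the same log2 values, without the planned voom weights, with an inter-gene correlation of 0.01 and again with the correlation estimated. Of 780 list tests 153 were called in the first way and 19 in the second. Membership of rhythmic genes was tested with Fisher's exact test, one-sided. Markers of other cell types were among the lists, and are given beside the gene groups they moved with.

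Fixed in advance were DESeq2 size factors, DESeq2 1.42.0 in place of the main test, no filter, a minimum fold of 1.5, the replicate number as a block, a joint fit over all arms of a table, the older edgeR settings and leaving out each replicate number. Chosen after seeing the data were edgeR 4.0.16 on the recovered reads, pseudocounts of 0.1 and 2, the deposited scaling, leaving out the shallow libraries, leaving out 2 ad libitum libraries that resembled each other's time point, leaving out a tunicamycin library, and the comparisons of Albumin-Cre with WT liver and of the vehicle arms between genotypes. On the recovered reads edgeR called 5383 daily means and 540 rhythm differences between arrhythmic and night feeding, 9041 and 339 between genotypes, and 2799 rhythmic genes in night-fed WT liver.

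The tests were tried on simulated data drawn from the libraries' own means. For arrhythmic against night feeding, over 12413 genes, limma recovered 42 of 50 genes changed by 1.5-fold and 50 of 50 changed by 2-fold, with 4 unchanged genes called. It recovered 16 of 50 rhythm differences of amplitude 0.5 and 48 of 50 of amplitude 1. For tunicamycin with arrhythmic against night feeding, over 12261 genes, these were 43, 49, 18 and 46 of 50. A rhythm difference of amplitude 0.5 was thus mostly missed at this size and depth.

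The positions of genes were taken from a GENCODE annotation of the same genome build by gene symbol.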

Results

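Gene expression was measured in the livers of male C57BL/6J mice by 3' mRNA sequencing, in which reads come from the 3' ends of polyadenylated transcripts. The mice were wild type (WT), lacked the clock transcription factor Bmal1 (gene symbol Arntl) in the whole body (BMKO), lacked Tsc1, a repressor of the growth-regulating kinase complex mTORC1, in the liver (TSKO), lacked Raptor (gene symbol Rptor), an essential subunit of mTORC1, in the liver (RPKO), or carried the Albumin-Cre transgene alone as controls for both liver knockouts. Food was given ad libitum, only at night, or arrhythmically over the day. Some mice received rapamycin, which inhibits mTORC1, or its vehicle. Others received AZD8055, an ATP-competitive mTOR inhibitor, at dawn or at dusk, and others tunicamycin, which blocks N-glycosylation and causes endoplasmic reticulum (ER) stress. The 282 libraries formed 16 arms. In 13 arms the livers were taken at zeitgeber time (ZT) 2, 6, 10, 14, 18 and 22 h, counted from lights on, with 3 libraries per time. The 3 tunicamycin arms were sampled at ZT 4, 10, 16 and 22 h with 4 libraries per time. The depth was 0.706 to 14.3 M reads per library (M, 10 to the power of 6; median 8.51 M) in the 13 arms and 4.85 to 10.1 M (median 7.71 M) in the tunicamycin arms.

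The targeted genes were examined in every arm. Tsc1 (chromosome 2, 28641228 to 28691167, GRCm38) had 14.6 ± 2.59 RPM (reads per M reads) in Albumin-Cre liver (mean ± SD within time points, n = 18) and 7.24 ± 1.53 in TSKO liver (n = 18), a log2 difference of -0.99 ± 0.08 (SE; limma adjusted p = 1.11e-12). Rptor (chromosome 11, 119602905 to 119899576) had 8.89 ± 1.41 in Albumin-Cre liver and 5.11 ± 1.74 in RPKO liver (n = 18 each), a log2 difference of -0.80 ± 0.10 (limma adjusted p = 2.25e-08). The remaining signal was not assigned to cell types, and non-hepatocytes keep the gene in an Albumin-Cre knockout. Arntl (chromosome 7, 113207465 to 113314126) had 13.1 ± 2.89 RPM in night-fed WT liver and 10.4 ± 3.08 in BMKO liver (n = 18 each). A 3' tag outside the deleted part does not check this deletion. The lowest and highest libraries were 0.177 and 26.6 in WT and 6.06 and 16.9 in BMKO, so the daily swing of this transcript was narrower in the libraries labelled BMKO. With vehicle Arntl had 8.996 ± 3.52 RPM in WT and 13.7 ± 3.79 in BMKO liver (n = 18 each), a log2 difference of 1.42 (limma adjusted p = 3.81e-10), and the fitted log2 difference without injection was 0.36 and not called.

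The feeding arms ask how far daily rhythms in liver depend on when the mice eat. In untreated night-fed WT liver 2701 of 12413 genes had a 24 h rhythm. Dbp, a clock-controlled transcription factor (chromosome 7, 45705088 to 45710203), had an amplitude of 3.15 ± 0.16 on the log2 scale (SE, n = 18) with a peak at ZT 10.03 (limma adjusted p = 2.48e-10). The amplitude is the distance from the mean to the peak. Rgs16, a regulator of G-protein signaling that responds to feeding, reached 3.09 ± 0.21, the nuclear receptor Nr1d1 2.76 ± 0.18 with a peak at ZT 6.42, and Arntl 2.28 ± 0.12 with a peak at ZT 21.4. Of the 21 core clock genes measured, 20 were rhythmic (20 when adjusted over the list alone, Fisher's exact test adjusted p = 3.3e-11). Heat shock chaperones and cochaperones were rhythmic in 19 of 19 (19 adjusted over the list alone, Fisher's exact test adjusted p = 9.9e-12), ER chaperones and unfolded protein response genes in 18 of 31 (21 adjusted over the list alone), and fatty acid synthesis genes in 13 of 19 (15 adjusted over the list alone). Under ad libitum feeding 2051 genes were rhythmic and under arrhythmic feeding 987, with 20 and 18 of the 21 core clock genes among them (20 and 19 adjusted over the list alone). Without replicate 1, 2 or 3 the counts were 1091 to 1436 under night, 410 to 1529 under ad libitum and 232 to 431 under arrhythmic feeding, and a joint fit of all arms gave 822 and 523 for the last 2. The number of rhythmic genes per arm is plotted for all arms, and the number with a peak-to-trough fold of at least 1.5 beside it.

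**Figure D1:**
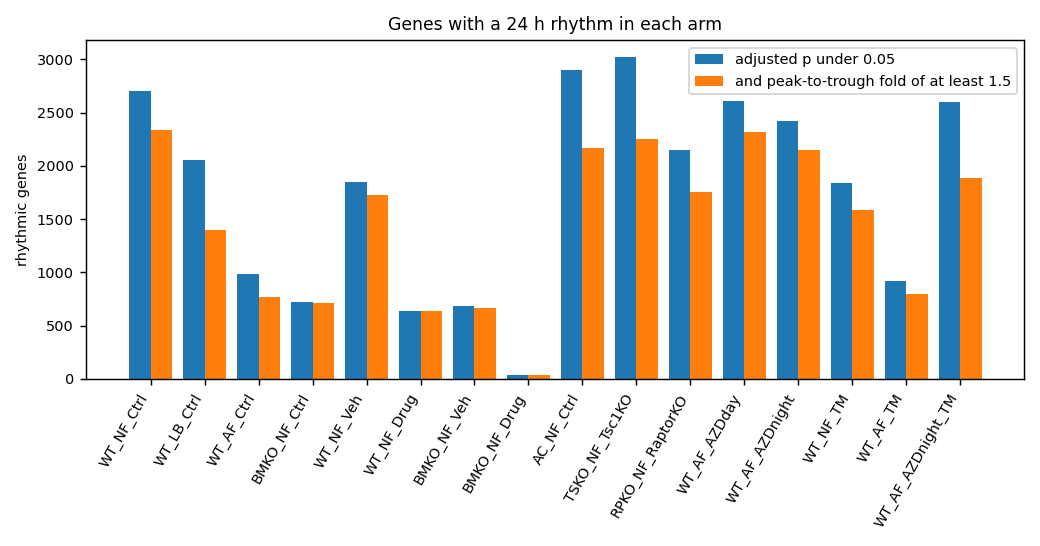
Number of genes with a 24 h rhythm in each of the 16 arms (vertical axis, genes; limma adjusted p under 0.05), as bars from 0, with a second bar for those that also have a fitted peak-to-trough fold of at least 1.5. The highest count was 3027 in TSKO and the lowest 34 in BMKO given rapamycin.

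Arrhythmic feeding lowered the daily mean of acute phase and metallothionein transcripts relative to night feeding. Saa2, a serum amyloid A gene of the acute phase, was lower by a log2 difference of -3.60 ± 0.19 (SE, n = 18 per arm; limma adjusted p = 8.72e-19), and the iron-binding protein Lcn2 by -2.68 ± 0.22 (limma adjusted p = 9.17e-13). Mt2 and Mt1, metal-binding proteins, differed by -3.46 ± 0.27 and -3.18 ± 0.23. Saa1 and Saa2, like Mt1 and Mt2, are close copies, so the split of reads between them is uncertain. Apob, the main protein of VLDL, rose by 1.21 ± 0.16 and Ceacam1, which promotes insulin clearance, by 1.24 ± 0.08. Among 18 acute phase genes 11 fell, 2 rose and the others did not pass (11 and 2 adjusted over the list alone). The camera set test gave adjusted p = 3.32e-05 for this list, and adjusted p = 0.475 with an estimated correlation. The untreated night-fed WT arm had a Saa2 mean of 160.5 RPM, against 96.3 in vehicle-injected night-fed WT, 86.1 in Albumin-Cre liver, 20.8 under ad libitum and 13.3 under arrhythmic feeding.

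Rhythms also differed between arrhythmic and night feeding in 577 genes, 539 with a lower amplitude under arrhythmic feeding and 38 with a higher one. Their median amplitude was 0.20 under arrhythmic and 0.51 under night feeding. The autophagy receptor-like gene Calcoco1 fell from an amplitude of 1.64 to 0.11 (limma adjusted p = 0.000135), the feeding-induced lipase regulator Angptl8 from 1.72 to 0.23, Alas1, the rate-limiting enzyme of heme synthesis, from 2.04 to 0.57, the secreted hepatokine Tsku from 1.81 to 0.43, and the glycogen-targeting phosphatase subunit Ppp1r3b from 1.86 to 0.50. The clock output gene Dbp went from 3.15 to 2.54 with the peak moving from ZT 10.03 to 8.72 (limma adjusted p = 0.0127), a call that did not pass without replicate 2 or 3. The night minus day difference was smaller under arrhythmic feeding for 10 of 19 heat shock genes (15 adjusted over the list alone) and for 10 of 31 ER chaperone genes, with 1 larger (15 and 1 adjusted over the list alone). Camera called both lists with an estimated correlation too, at adjusted p = 0.0229 and 0.0103. The daily means of 2939 genes were higher and of 2522 lower under arrhythmic feeding, 528 and 413 of them by at least 1.5-fold. Residuals of night-fed libraries with the same replicate number were correlated between times (median 0.325), so SE and p-values may be too small. The night-fed arm had a median of 5.76 M reads and the arrhythmic arm 8.74 M, and an effect of depth was not tested here. Without replicate 1, 2 or 3 the rhythm differences numbered 33 to 265 and the daily mean differences 3256 to 4952, and a joint fit gave 199 rhythm differences. Daily means also differed for 4379 genes between untreated Albumin-Cre and WT liver under night feeding, but those arms were scaled in separate sets. The arrhythmic and night-fed arms were scaled in the same set, so that count is no direct measure of background for them.

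Ad libitum feeding was compared with the same night-fed libraries, whose high Saa2, correlated residuals and lower depth are given above. The ad libitum arm had a median of 9.61 M reads. Saa2 differed by -3.19 ± 0.19, Mt2 by -3.27 ± 0.27, Mt1 by -2.97 ± 0.23 and Lcn2 by -2.62 ± 0.22 (SE, n = 18 per arm; limma adjusted p = 4.1e-13 for Lcn2). Among 18 acute phase genes 10 were lower and 1 higher (10 and 1 adjusted over the list alone), with camera adjusted p = 0.000713 and adjusted p = 0.778 with an estimated correlation. Among 49 ribosomal protein genes 31 were lower and 4 higher (32 and 4 adjusted over the list alone), with camera adjusted p = 1.74e-08 and adjusted p = 0.778 with an estimated correlation. Rhythms differed in 106 genes, and in 104 of these the amplitude was lower. Mid1ip1, an activator of fatty acid synthesis, went from 1.14 to 0.16 (limma adjusted p = 8.88e-05), Tsku from 1.81 to 0.64, the cold-inducible RNA-binding protein Cirbp from 1.22 to 0.33, and Calcoco1 from 1.64 to 0.40. The night minus day difference was smaller for 10 of 19 heat shock genes (17 adjusted over the list alone, camera adjusted p = 0.0117 with an estimated correlation) and for 4 of 31 ER chaperone genes (10 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.0433 with an estimated correlation). In all, 3505 daily means were higher and 3069 lower, 843 and 721 by at least 1.5-fold. The rhythm differences numbered 1 to 25 without replicate 1, 2 or 3, 174 by DESeq2 and 68 without ad libitum replicate 3 at ZT 10 and at ZT 14, which resembled each other's time point.

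Without Bmal1 most core clock genes were not called rhythmic. Of the 21 measured, 4 were rhythmic in BMKO liver (6 adjusted over the list alone) against 20 in WT, among them the repressors Per1 and Per2 and the deubiquitinase Usp2, with amplitudes of 1.22, 1.02 and 0.89 against 1.57, 1.75 and 2.63 in WT. The amplitude of Dbp was 3.15 in WT and 0.25 in BMKO liver (limma adjusted p = 3.46e-20), that of Nr1d1 2.76 and 0.34, of the clock paralog Npas2 1.79 and 0.16, of the repressors Per3 and Cry1 1.93 and 0.37 and 1.63 and 0.37, and of Arntl itself 2.28 and 0.14. Rhythms differed in 376 genes, with a lower amplitude in BMKO for 260 and a higher one for 116. Rab30, a small GTPase, had amplitudes of 0.12 in WT and 1.13 in BMKO (limma adjusted p = 0.000681), the DNA replication helicase subunit Mcm6 0.22 and 1.29, and the mitochondrial carrier Slc25a25 0.23 and 1.51. Without replicate 1, 2 or 3 the count was 81 to 469, and Rab30, Mcm6 and Slc25a25 no longer passed without replicate 2. Shuffled arm labels gave as many differences in 12 of 100 splits, and in 1 of 100 with each arm's mean subtracted first.

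Daily means shifted with the same genotypes. The nuclear receptors Nr1d2 and Nr1d1 fell in BMKO by -3.43 ± 0.17 and -1.92 ± 0.18, and the clock genes Npas2 and Cry1 rose by 2.94 ± 0.14 and 2.05 ± 0.10 (SE, n = 18 per arm). The transcription factor Tox2 was higher by 6.10 ± 0.23 (limma adjusted p = 1.56e-37), the neurotrophin receptor Ntrk2 by 4.49 ± 0.26, the adipokine Serpina12 by 4.36 ± 0.27, the cell cycle inhibitor Cdkn1a by 4.05 ± 0.20 and the phosphate transporter Slc34a2 by 3.99 ± 0.24. The membrane peptidase Mme was lower by -4.78 ± 0.17 and the collagen Col27a1 by -3.50 ± 0.18. The same differences were measured in separate animals given vehicle, where Tox2 differed by 4.45, Ntrk2 by 4.00, Cdkn1a by 2.67, Mme by -3.48 and Nr1d2 by -2.52. Other differences did not recur there. Saa2 differed by -4.20 ± 0.60 in untreated mice and by 0.57 in the vehicle arms, Snord89 by 4.93 and -0.29, and Per1 by 0.71 and -0.06. In untreated mice 4222 genes were higher and 4693 lower in BMKO, 2620 and 2976 by at least 1.5-fold. Between the vehicle arms 1248 were higher and 1453 lower, and of the 8915 genes called in untreated mice 59.2% had the same sign there. Over these 8915 genes the slope of the vehicle difference on the untreated difference was 0.179. The Kupffer cell list, a marker of liver macrophages, had 8 of 12 genes lower and 2 higher in untreated BMKO (camera adjusted p = 0.324).

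Rhythms that persist without Bmal1 were counted as genes rhythmic in both genotypes. In night-fed BMKO liver 718 genes were rhythmic. The largest amplitudes included Depp1, a FOXO target, at 2.71 ± 0.24 with a peak at ZT 4.64 (SE, n = 18; limma adjusted p = 1.26e-05), the fatty acid transporter Mfsd2a at 1.76 ± 0.26, Angptl8 at 1.66 ± 0.15 with a peak at ZT 18.9, and the ER stress gene Creld2 at 1.63 ± 0.22. Both genotypes shared 491 rhythmic genes, against 156.2 for independent lists, and 414 of them peaked within 4 h of each other, against 52.1 for independent lists and peak times. Among these 414 were 12 of 19 heat shock genes (Fisher's exact test adjusted p = 1.98e-12), 14 of 31 ER chaperone genes (4.02e-12), 8 of 19 fatty acid synthesis genes (7.83e-07), 8 of 25 cholesterol synthesis genes (7.05e-06), 8 of 35 ribosome biogenesis genes (9.15e-05) and 4 of 23 fatty acid oxidation genes (0.0326). Angptl8 peaked at ZT 17.9 in WT and 18.9 in BMKO, Tsku at 15.7 and 16.2, the chaperone Hsph1 at 16.6 and 17.8, and the fatty acid synthase Fasn at 20.2 and 22.04. The BMKO count was 1216 without the 3 shallow libraries, 1344 by DESeq2, 3216 in a joint fit with a pooled spread and 66 to 528 without replicate 1, 2 or 3, which left 50 to 230 shared genes. The median residual SD was 0.426 in BMKO, the highest of all arms, and 0.316 in WT.

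The 414 shared genes were followed into the other arms. Their median amplitude was 0.56 in night-fed WT and 0.61 in BMKO liver, where they were selected, 0.30 under ad libitum and 0.23 under arrhythmic feeding. In arms not used for the selection it was 0.54 in WT given vehicle and 0.38 in WT given rapamycin, 0.48 in BMKO given vehicle and 0.27 in BMKO given rapamycin. It was 0.51 in both Albumin-Cre and TSKO liver and 0.49 in RPKO liver, where 409 of the genes were tested. The rhythm itself differed in 177 of them under arrhythmic feeding (296 adjusted over the list alone) and in 54 under ad libitum feeding (181 adjusted over the list alone), each against night feeding. Rapamycin changed the rhythm of 15 in BMKO (65 adjusted over the list alone). In WT limma called 0 of them after rapamycin, with 80 at an unadjusted p under 0.05 and 11 adjusted over the list alone. Selection on the night-fed WT arm favors high amplitudes there, so lower values in the other feeding arms follow in part from the selection.

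**Figure D2:**
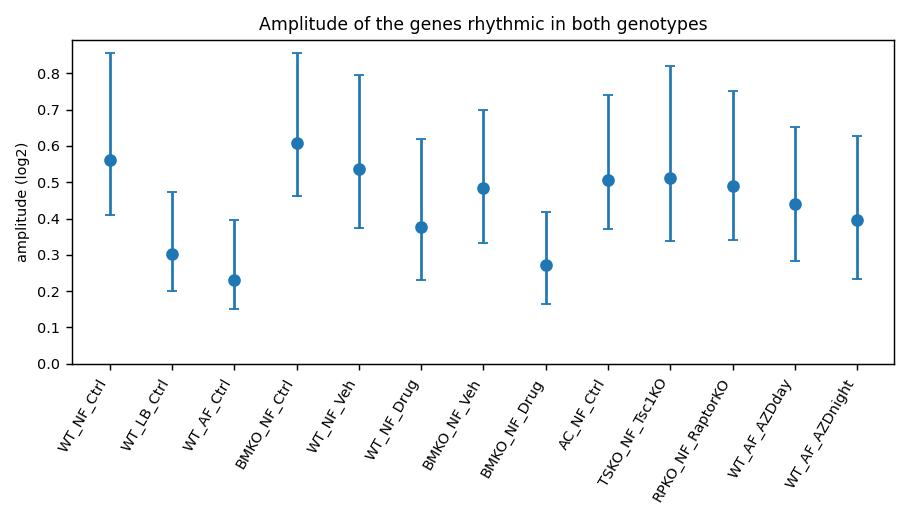
Amplitude (log2, mean to peak) of the 414 genes rhythmic in night-fed WT and BMKO liver with peaks within 4 h, in each of the 13 arms sampled at 6 times. In RPKO 409 of them were tested. Points are medians over genes and lines span the quartiles. The medians were 0.48 in BMKO given vehicle and 0.27 in BMKO given rapamycin.

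Vehicle injection was compared with no injection over WT and BMKO mice together. Ppp2r3c, a phosphatase regulatory subunit, rose by 1.34 ± 0.19 (SE; limma adjusted p = 1.25e-08) and the ribosome biogenesis factor Rbis by 1.24 ± 0.11. Csad, an enzyme of taurine synthesis, was lower by -1.19 ± 0.19, the tubulin ligase Ttll3 by -1.23 ± 0.11 and the mediator subunit Med16 by -1.07 ± 0.09. Among 25 cholesterol synthesis genes 14 were lower and none rose (15 lower adjusted over the list alone), with camera adjusted p = 3.29e-05 and adjusted p = 0.935 with an estimated correlation. The daily means of 2699 genes were higher and of 2458 lower, 446 and 198 by at least 1.5-fold. Higher calls made up 52.3%, and 70.7% with the deposited scaling. The total was 5157, and 2816 to 6894 without replicate 1, 2 or 3. The injected and uninjected arms were scaled by the authors in separate sets, and untreated Albumin-Cre and WT arms of separate sets differed in 4379 genes, so an effect of the set is not told apart from that of the vehicle.

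In night-fed WT mice given rapamycin the organic anion transporter Slc22a7 rose by 2.17 ± 0.24 (SE, n = 18 per arm; limma adjusted p = 1.14e-10), the apolipoprotein Apoa4 by 1.83 ± 0.22, the lipid droplet protein Cidec by 1.73 ± 0.25 and Serpina12 by 1.59 ± 0.27. Chrna4, a nicotinic receptor subunit, fell by -2.76 ± 0.28, the mTORC1 inhibitor Ddit4 by -1.59 ± 0.22 and Tsc1 by -0.60 ± 0.08, from 13.96 ± 2.40 to 9.01 ± 1.31 RPM (SD, n = 18 each). Among 23 fatty acid oxidation genes 12 rose and none fell (12 adjusted over the list alone), among them the lipid droplet coat protein Plin2 by 0.75 ± 0.13 and the mitochondrial carnitine carrier Slc25a20 by 0.54 ± 0.10. Camera gave adjusted p = 1.38e-06 for this list, and adjusted p = 0.113 with an estimated correlation. Endothelial markers were lower in 5 of 12 genes (camera adjusted p = 0.0322, and adjusted p = 0.285 with an estimated correlation). Rapamycin raised the daily means of 1247 genes and lowered those of 1075, 287 and 370 by at least 1.5-fold, with 1275 to 1766 in all without replicate 1, 2 or 3.

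Rhythms in WT liver were compared between rapamycin and vehicle in the same way. Dbp had amplitudes of 3.23 ± 0.11 with rapamycin and 3.16 ± 0.15 with vehicle, peaking at ZT 10.3 and 10.1. The night minus day difference of fatty acid synthesis genes was larger with rapamycin in 0 of 19 genes by limma and in 9 adjusted over the list alone, and camera called the list at adjusted p = 9.02e-21 and at adjusted p = 0.0037 with an estimated correlation. Of the same 19 genes 12 were rhythmic with vehicle and 6 with rapamycin (15 and 11 adjusted over the list alone), with median amplitudes of 0.79 and 0.45, and this contrast was not tested. Over all 12413 genes limma called 0 rhythm differences, edgeR 0 and DESeq2 13. At an unadjusted p under 0.05 limma gave 680, a share close to the 0.05 that chance gives. The rhythmic genes numbered 1853 with vehicle and 636 with rapamycin, 489 to 1035 and 149 to 730 without replicate 1, 2 or 3. With rapamycin they were 1957 in a joint fit with a pooled spread, 1057 by DESeq2 and 987 with the replicate number as a block, and the median residual SD was 0.398 against 0.329 with vehicle, so a lower number with rapamycin was not established.

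In BMKO mice given rapamycin Cyp2b10 and Cyp2c55, cytochromes P450 that respond to foreign compounds, fell by -2.49 ± 0.26 and -1.796 ± 0.21 (SE, n = 18 per arm; limma adjusted p = 3.46e-11 and 8.34e-10), though Cyp2b10 has close copies and its value is uncertain. Mcm6 fell by -1.62 ± 0.22, and 4 of 11 proliferation genes fell and none rose (7 lower adjusted over the list alone), with camera adjusted p = 0.00022 and adjusted p = 0.187 with an estimated correlation. Slc22a7 rose by 1.27 ± 0.24 and the vesicular glutamate transporter Slc17a8 by 1.73 ± 0.22. Xenobiotic metabolism genes were lower in 5 of 15 (7 lower and 1 higher adjusted over the list alone), with camera adjusted p = 0.0373 with an estimated correlation, and pericentral hepatocyte markers in 5 of 11 (6 adjusted over the list alone), with adjusted p = 0.0352 with an estimated correlation. In all, 774 genes had higher and 694 lower daily means, 195 and 240 by at least 1.5-fold, with 593 to 941 in all without replicate 1, 2 or 3. Residuals of libraries with the same replicate number were correlated between times (median 0.555 with vehicle and 0.285 with rapamycin). The tests took libraries as independent, so these SE and p-values may be too small.

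Rapamycin changed 40 rhythms in BMKO liver, 39 of them toward a lower amplitude. Tsku went from 1.61 with vehicle to 0.17 with rapamycin (limma adjusted p = 0.000178), the nucleolar factors Nolc1 from 0.87 to 0.11 and Nop56 from 0.78 to 0.17, the kinase Pim1 from 0.77 to 0.15, and the transferrin receptor Tfrc from 1.41 to 0.59. Of 35 ribosome biogenesis genes 2 had a smaller night minus day difference (8 adjusted over the list alone), with camera adjusted p = 9.21e-07 and adjusted p = 0.0355 with an estimated correlation. Rhythmic genes numbered 683 with vehicle and 34 with rapamycin. Those 34 included Fasn at an amplitude of 1.22 ± 0.17 (limma adjusted p = 0.011), the lipogenic genes Thrsp at 1.04, Acly at 0.80 and Elovl6 at 0.83, and Hsph1 at 0.81. Without replicate 1, 2 or 3 the rhythm differences were 2 to 6 and the rhythmic genes 12 to 1552 with vehicle and 0 to 9 with rapamycin, so the contrast between these arms rested on few libraries. DESeq2 called 79 differences and 225 rhythmic genes with rapamycin, and with the replicate number as a block, which marked a set in the vehicle arm (median correlation 0.555 between times), 2524 genes were rhythmic with vehicle and 130 with rapamycin.

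**Figure D3:**
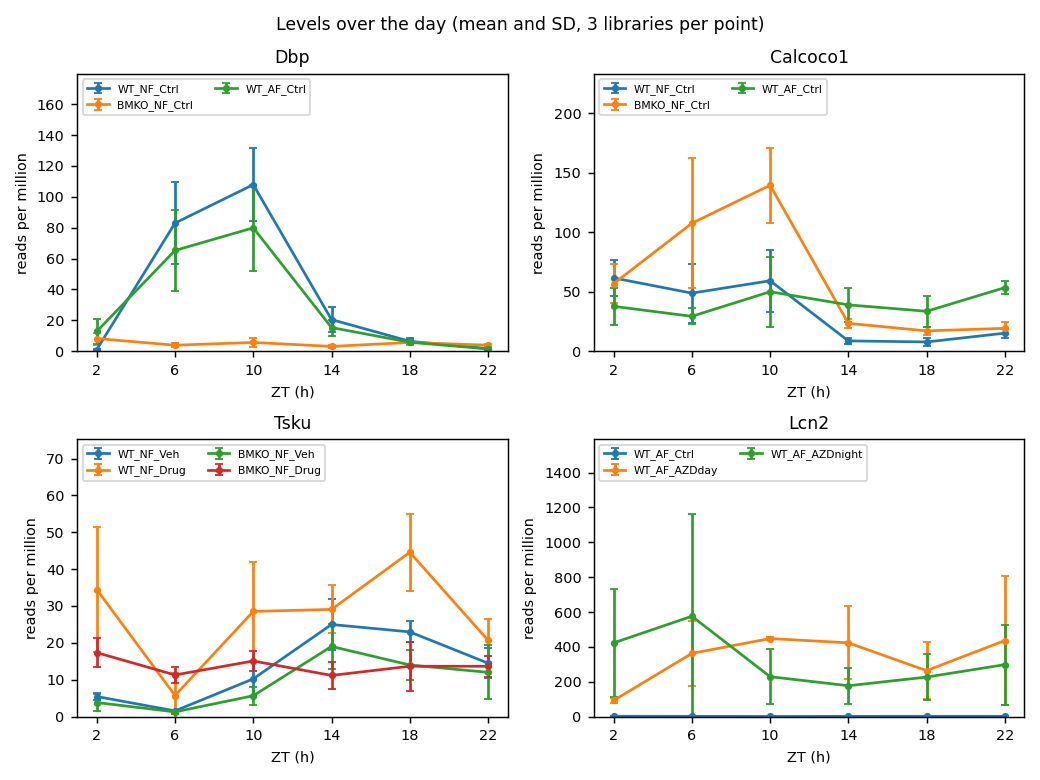
Mean ± SD of 3 libraries at each ZT (horizontal axis, h) in RPM for Dbp and Calcoco1 in night-fed WT, night-fed BMKO and arrhythmically fed WT liver, Tsku in WT and BMKO liver with vehicle or rapamycin, and Lcn2 with and without AZD8055 under arrhythmic feeding. Fitted amplitudes of Tsku were 1.61 in BMKO with vehicle and 0.17 with rapamycin, and Dbp had an amplitude of 0.25 in BMKO.

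The effect of rapamycin differed between BMKO and WT for 1774 genes, higher in BMKO for 953 and lower for 821. G0s2, an inhibitor of lipolysis, changed by 1.35 in WT and -0.93 in BMKO, a difference of -2.29 ± 0.40 (SE; limma adjusted p = 0.000164), and Cidec by 1.73 and -0.30, a difference of -2.03 ± 0.35. The mitochondrial carrier Slc25a42 changed by 1.71 and -0.43 (difference -2.14 ± 0.50). Fatty acid oxidation genes had a lower response in BMKO in 11 of 23 (14 adjusted over the list alone), with camera adjusted p = 7.14e-07 and adjusted p = 0.244 with an estimated correlation. Without replicate 1 the count was 124, and the difference for Slc25a42 then did not pass.

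Loss of Tsc1 in the liver, which releases mTORC1 from inhibition, raised lysosomal genes. Of 27 lysosome and autophagy genes 20 rose and none fell (20 adjusted over the list alone), among them the autophagy protein Gabarapl1 by 1.35 ± 0.08 and the lysosomal membrane protein Lamp1 by 0.63 ± 0.05 (SE, n = 18 per arm). Camera called this list at adjusted p = 2.77e-05 with an estimated correlation. The largest rises included the collagen Col5a2 at 5.38 ± 0.18 (limma adjusted p = 3.51e-26), the secreted peroxidase Gpx3 at 4.61 ± 0.28, the lysophospholipase Gdpd3 at 4.48 ± 0.19, the peptide hormone Enho at 3.52 ± 0.25 and the lysosomal GTPase Rragd at 3.26 ± 0.16. Serpina12 fell by -3.15 ± 0.28, Fitm1, a lipid droplet protein, by -2.42 ± 0.18, Serpina7, a thyroxine carrier, by -2.32 ± 0.18 and haptoglobin (Hp) by -2.31 ± 0.13. Ribosomal protein genes fell in 37 of 49 and rose in 1 (37 and 1 adjusted over the list alone), such as Rpl3 by -0.67 ± 0.05 and Rps25 by -0.60 ± 0.05, with camera adjusted p = 3.67e-16 and adjusted p = 0.107 with an estimated correlation. Fatty acid oxidation genes fell in 13 of 23 and rose in 1 (13 and 2 adjusted over the list alone), such as Acaa2 by -0.68 ± 0.05, with camera adjusted p = 5.9e-06 and adjusted p = 0.107 with an estimated correlation. The amino acid stress genes Asns and Ddit4 rose by 3.15 ± 0.31 and 2.30 ± 0.12, and the cholesterol synthesis enzyme Fdps by 1.13 ± 0.13.

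Few differences in daily rhythm were called between TSKO liver and the control. In simulated data of the feeding arms most rhythm differences of amplitude 0.5 were missed, so differences of that size are not excluded here. Dbp had amplitudes of 2.94 ± 0.11 in TSKO and 2.89 ± 0.15 in Albumin-Cre liver, and the fatty acid elongase Elovl3 2.67 ± 0.17 and 2.25 ± 0.15. In TSKO 3027 genes were rhythmic and in the control 2898, with 1363 to 1677 and 995 to 1517 without replicate 1, 2 or 3. Meiob, a meiotic gene and the 1 gene that limma called for a rhythm difference, had amplitudes of 0.54 and 0.80 (adjusted p = 0.0379). At an unadjusted p under 0.05 there were 696 of 12267 genes, a share close to the 0.05 that chance gives. With edgeR 3 were called and with DESeq2 8, and without any of replicates 1 to 3 limma called 0. Daily means were higher for 2288 genes and lower for 2193 in TSKO, 509 and 426 by at least 1.5-fold. Between the untreated Albumin-Cre and WT arms 4379 differed, but those were scaled in separate sets. TSKO and Albumin-Cre were scaled in the same set, so that count is no direct measure of background for them.

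In liver without Raptor, whose loss disables mTORC1, immediate early genes were higher than in Albumin-Cre liver. Egr1 rose by 1.48 ± 0.32, Junb by 0.91 ± 0.13 and Klf6 by 0.70 ± 0.09 (SE, n = 18 per arm), and 7 of 9 genes of this list rose (camera adjusted p = 0.0279, and adjusted p = 0.895 with an estimated correlation). The sterol synthesis enzymes Idi1 and Tm7sf2 were higher by 1.19 ± 0.16 and 0.91 ± 0.07 (limma adjusted p = 1.45e-14 for Tm7sf2). Ribosomal protein genes rose in 28 of 49 and fell in 5 (28 and 6 adjusted over the list alone), such as Rpsa by 0.86 ± 0.07 and Rpl3 by 0.66 ± 0.05, with camera adjusted p = 4.33e-05 and adjusted p = 0.907 with an estimated correlation. In this arm 78 genes, 75 of them unnamed gene models or pseudogenes, were near 0, so reads may have been counted otherwise than in the control, and the ribosomal protein values, whose genes have many pseudogenes, are uncertain. The macrophage list rose in 5 of 12 genes (camera adjusted p = 0.0598). Dbp had an amplitude of 3.53 ± 0.10 with a peak at ZT 10.8 in RPKO liver. Over all 12267 genes limma and edgeR called 0 rhythm differences and DESeq2 2. At an unadjusted p under 0.05 limma gave 542, a share below the 0.05 that chance gives. Daily means were higher for 2424 and lower for 2771 of the 12267 genes tested, and higher calls made up 46.7%, but 12.1% with the deposited scaling, under which the median of all genes was -0.23 against -0.01. RPKO and Albumin-Cre libraries were scaled in separate sets too, so an effect of the set is not told apart from that of the genotype in these daily means.

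AZD8055 under arrhythmic feeding asks whether an mTOR inhibitor given at a fixed time of day can impose a rhythm. It was compared with uninjected mice, since no vehicle arm under this feeding was analysed here, so injection and drug are not told apart. Given at dawn it raised acute phase genes in 17 of 18 (17 adjusted over the list alone, camera adjusted p = 5.12e-30, and adjusted p = 0.00465 with an estimated correlation). Saa2 rose by 8.83 ± 0.41, Lcn2 by 7.24 ± 0.38, the acid glycoprotein Orm2 by 3.45 ± 0.14 and Fgl1, a hepatokine, by 3.05 ± 0.13 (SE, n = 18 per arm; limma adjusted p = 2.48e-19 for Lcn2). Mt2 and Mt1 rose by 7.02 ± 0.36 and 6.52 ± 0.30. Of the ER chaperone genes 23 of 31 rose and 2 fell (24 and 2 adjusted over the list alone), such as Hyou1 by 1.04 ± 0.09 and Creld2 by 1.22 ± 0.14, with camera adjusted p = 1.18e-08 and adjusted p = 0.231 with an estimated correlation. Elovl3 fell by -1.99 ± 0.30 and male-biased liver genes in 8 of 11 (9 adjusted over the list alone, adjusted p = 0.242 with an estimated correlation). Erythroid markers were lower in 5 of 5 and lymphocyte markers in 3 of 3 (camera adjusted p = 0.0166 and 0.0066, and adjusted p = 0.482 and 0.0688 with an estimated correlation). Daily means were higher for 2595 genes and lower for 2497, with 51.0% higher, or 67.4% with the deposited scaling, and 3286 to 4391 in all without replicate 1, 2 or 3. The AZD8055 arms and their control were scaled in separate sets, as were the Albumin-Cre and WT arms that differed in 4379 genes.

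Between dawn AZD8055 and uninjected mice 1819 rhythms differed, 1501 of them with a higher amplitude after AZD8055. Effects of a timed injection are part of these differences. The chemokine Cxcl1 went from 0.18 to 3.40 with a peak at ZT 4.91, the cytokine signaling inhibitor Socs3 from 0.38 to 2.46, the immediate early genes Junb from 0.37 to 2.32 and Egr1 from 0.59 to 2.18, and the stress gene Chac1 from 0.30 to 1.95. The night minus day difference was smaller or more negative in 5 of 9 immediate early genes (7 adjusted over the list alone, camera adjusted p = 0.00232 with an estimated correlation). Clock genes peaked earlier, Nr1d1 at ZT 2.52 against 5.74 (limma adjusted p = 7.49e-06) and Dbp at 6.04 against 8.72 (limma adjusted p = 0.00563). The rhythm differences numbered 598 to 1121 without replicate 1, 2 or 3. The calls for Dbp without replicate 1 or 2 and for Chac1 without replicate 3 did not pass. Amplitudes of the clock output genes Noct and Usp2 fell from 1.54 to 0.54 and from 2.33 to 1.13.

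Given at dusk, AZD8055 was again compared with uninjected mice, and the same kinds of genes were higher over the day. Acute phase genes rose in 17 of 18 (17 adjusted over the list alone, camera adjusted p = 0.0336 with an estimated correlation), Saa2 by 8.504 ± 0.41, Lcn2 by 7.10 ± 0.38 and the glycoproteins Lrg1 and A1bg by 3.12 ± 0.14 and 3.31 ± 0.22 (SE, n = 18 per arm). ER chaperone genes rose in 20 of 31 and fell in 2 (22 and 2 adjusted over the list alone), such as Sdf2l1 by 1.82 ± 0.22, with camera adjusted p = 0.000273 and adjusted p = 0.745 with an estimated correlation. The macrophage list rose in 7 of 12 (camera adjusted p = 0.0524). Rhythms differed from uninjected mice in 711 genes, 608 with a higher amplitude, such as Creld2 from 0.14 to 1.55 with a peak at ZT 23.1 (limma adjusted p = 0.000114), the glycogen-targeting subunit Ppp1r3g from 0.96 to 2.94 and the stress kinase Plk3 from 0.13 to 1.57. Daily means were higher for 3346 genes and lower for 2963, with 53.04% higher, or 63.5% with the deposited scaling, again between separately scaled sets. The rhythm differences numbered 109 to 169 without replicate 1, 2 or 3, and Ppp1r3g did not pass in edgeR.

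Dawn and dusk injection were then set against each other directly. Without vehicle arms, the time of injection is not told apart from the time of mTOR inhibition. Their rhythms differed in 5169 genes, and in 4176 of these the peaks were more than 8 h apart. Cxcl1 peaked at ZT 4.91 after dawn and 14.02 after dusk injection, and Socs3 at 5.33 and 15.9. Thrsp had amplitudes of 0.41 after dawn and 1.44 after dusk injection and Cdkn1a 0.51 and 2.37. Immediate early genes had a higher night minus day difference after dusk injection in 7 of 9 (8 adjusted over the list alone, camera adjusted p = 0.00476 with an estimated correlation), and cholesterol synthesis genes a lower one in 17 of 25 (21 adjusted over the list alone, adjusted p = 0.105 with an estimated correlation). Daily means differed less, with 246 genes higher and 253 lower after dusk injection. These were 4 to 446 in all, and the rhythm differences 3325 to 3802, without replicate 1, 2 or 3.

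Genes rhythmic after both injection times were sorted by their peaks. Of 1336 such genes, against 508.4 for independent lists, 75.8% peaked more than 8 h apart and 57 genes peaked within 4 h. Of the 17 core clock genes rhythmic in both arms 11 peaked within 4 h and 0 more than 8 h apart. Differences between lists were not tested. More than 8 h apart were 13 of 14 ER chaperone genes, 12 of 14 cholesterol synthesis genes, 8 of 8 ribosome biogenesis genes, 7 of 7 lysosome genes, 7 of 7 acute phase genes, 5 of 5 heat shock genes, 5 of 5 fatty acid oxidation genes, 7 of 9 gluconeogenesis genes, 5 of 6 immediate early genes, 4 of 5 ATF4 stress genes, 3 of 5 xenobiotic metabolism genes, 3 of 4 fatty acid synthesis genes and 0 of 2 bile acid genes, and the other lists had at most 2 such genes. Of 505 genes rhythmic under night feeding whose rhythm differed under arrhythmic feeding, 287 were rhythmic after dawn injection, and 59.9% of these peaked within 4 h of their night-fed peak, against 26.5 to 45.3% in 1000 shuffles of the peaks among genes. After dusk injection 258 were rhythmic and 25.6% peaked within 4 h, against 20.9 to 39.2% in the shuffles. In arrhythmically fed mice without injection 118 were rhythmic and 76.3% peaked within 4 h. With all genes rhythmic under night feeding as the set, the shares within 4 h were 48.2% after dawn and 58.1% after dusk injection, so the order of the injection times depended on the set. Genes are not independent replicates.

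**Figure D4:**
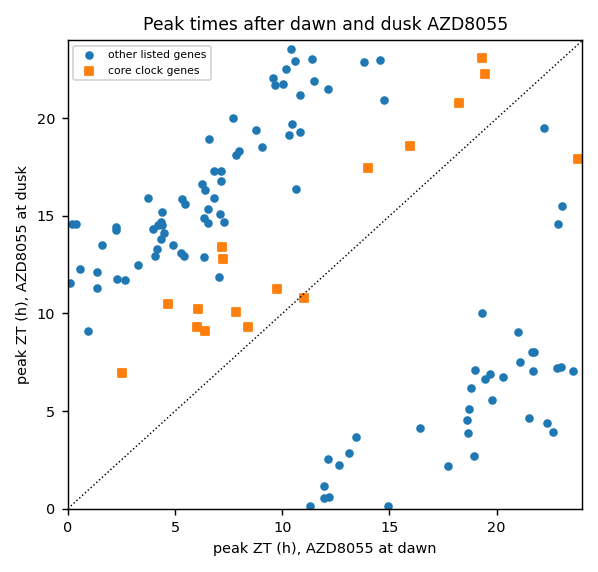
Peak ZT (h) after dawn injection (horizontal axis) and after dusk injection (vertical axis) of listed genes rhythmic in both AZD8055 arms, each point a gene, with core clock genes as squares and a dotted line where both peaks are equal. Of the 17 core clock genes 11 peaked within 4 h in both arms, while 13 of 14 ER chaperone genes peaked more than 8 h apart.

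With tunicamycin in WT mice, arrhythmic and night feeding differed in rhythm more than in level. Hmgcs1, an early enzyme of cholesterol synthesis, had an amplitude of 1.26 under night and 0.25 under arrhythmic feeding (limma adjusted p = 1.05e-06), while the lipogenic gene Thrsp had 0.20 and 1.31. Dbp went from 3.80 to 2.77 with its peak at ZT 12.9 and 8.94 (limma adjusted p = 7.93e-09), and the water channel Aqp8 from 1.68 to 0.62. Of the 21 core clock genes 7 had a lower night minus day difference under arrhythmic feeding and 1 a higher one (10 and 2 adjusted over the list alone, camera adjusted p = 0.00263 with an estimated correlation). Rhythms differed in 535 of 12261 genes, 413 with a lower amplitude under arrhythmic feeding, and daily means in 68, 30 higher and 38 lower, such as Csad by 0.92 ± 0.18 (SE, n = 16 per arm; limma adjusted p = 0.00637). No mice without tunicamycin were in this set of libraries. Night-fed replicate 2 at ZT 16 had 5112 RPM of the ER chaperone Hspa5 against 10590 to 11790 in the other 3 libraries, and 467.8 of Ddit3 against 1365 to 1720. Without it 2450 genes were rhythmic in the night-fed arm, against 1840, and 536 rhythms and 68 daily means differed. Without replicate 1, 2, 3 or 4 the rhythm differences numbered 150 to 411 and the daily mean differences 13 to 67, and DESeq2 called 129 daily means.

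Dusk AZD8055 was also given to arrhythmically fed mice with tunicamycin. No arm with tunicamycin and the vehicle of AZD8055 was analysed here, so injection and drug are not told apart. Acute phase genes rose in 15 of 18 relative to tunicamycin alone (15 adjusted over the list alone, camera adjusted p = 0.0346 with an estimated correlation), Saa2 by 4.22 ± 0.68, Lcn2 by 3.21 ± 0.46, Orm2 by 2.005 ± 0.19, Fgl1 by 1.91 ± 0.19 and Cxcl1 by 1.70 ± 0.28 (SE, n = 16 per arm; limma adjusted p = 4.02e-05 for Cxcl1). Ribosomal protein genes rose in 30 of 49 (41 adjusted over the list alone, adjusted p = 0.0346 with an estimated correlation). Male-biased liver genes fell in 8 of 11 (10 adjusted over the list alone, adjusted p = 0.0439 with an estimated correlation). Rgs16 fell by -1.63 ± 0.36, Elovl3 by -1.57 ± 0.24 and the keratin Krt23 by -1.81 ± 0.26. Neutrophil markers were higher in 3 of 3 and endothelial markers lower in 3 of 12 (camera adjusted p = 0.000289 and 0.00199, and adjusted p = 0.0661 and 0.0666 with an estimated correlation). In total 521 genes were higher and 572 lower, with 398 to 864 in all without replicate 1, 2, 3 or 4. Rhythms differed in 4 genes, the tight junction protein Cldn2 with amplitudes of 0.54 for tunicamycin alone and 0.23 with AZD8055, the methyltransferase Bhmt2 with 0.32 and 0.24, Tkfc with 0.32 and 0.55 and the thymidine kinase Tk1 with 0.59 and 0.73, and there were 1201 at an unadjusted p under 0.05. DESeq2 called 35 and edgeR 4, and without night-fed replicate 2 at ZT 16, which shares the estimate of the spread, limma called 29.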

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

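The tests of exchanged labels, of the spread of clock phase, of the genes called in both sets of animals, of residual spread and of amplitudes were chosen only after the result was seen.

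A sample far from the others of its group was looked for in 72 tests, over 12 groups of 4 libraries and 6 items, of which about 1 in 20 passes by chance. Arntl in tunicamycin-treated night-fed WT liver at ZT 22, replicate 2, was 31.5 RPM, against 23.0 to 24.1 in the others. Tsc1 in tunicamycin-treated arrhythmically fed liver at ZT 16, replicate 1, was 13.1 RPM, against 9.37 to 9.91. Hspa5 in liver with tunicamycin and dusk AZD8055 at ZT 4, replicate 1, was 8179 RPM, against 9466 to 9726. Replicate 2 of that arm at ZT 16 had 8.95 M reads, against 6.76 to 7.06 M.

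The response to rapamycin differed between groups, being higher in BMKO than in WT for 953 genes and lower for 821. Genes among those with the largest differences were the organic anion transporter Slco1a5 at 1.5 and, in the other direction, G0s2 at -2.29, Slc20a2 at -2.23, Apba3 at -2.22 and Slc25a22 at -2.14. Slc20a2, Apba3 and Slc25a22 were not called by DESeq2 or by edgeR on the recovered reads.

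Replicate 3 at ZT 10 and replicate 3 at ZT 14 of the ad libitum arm each resembled the other time point. The number of these 2 libraries that correlated best with the other's group was 2, and their clock times, read from clock genes, were off by 3.2 and -4.0 h. The smaller of these shifts was 1.78 times the largest among the other libraries of the arm. An exchange of the 2 labels would give these values. Single arrhythmically fed libraries reached 3.5 h, but the median of that arm was 1.45 h, so part of that shift belonged to the whole arm. The 2 ad libitum libraries were picked because they stood apart, so spread of clock phase between animals was not excluded. They were kept as labelled.

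In all, 8915 daily means differed between untreated BMKO and WT liver. Of the genes called, 59.2% had the same sign between the vehicle arms, which are other animals and were scaled in 2 separate sets, and the 2 control arms with an intact clock differed in 0.491 times as many genes. The first value met the prediction for batches of libraries as the whole cause of the count. The second met that for batches as part of the cause, but those control arms were scaled in separate sets. Untreated BMKO and WT were scaled in the same set, so the second value cannot decide on batches within a set. Of the genes called in both sets of animals 76.1% had the same sign, 1577 genes against 973.8 for independent lists, with 494 of opposite sign. These values argue against batches as the whole cause for the genes called in both. Loss of Bmal1, the biological explanation, may hold for part of them, and batches were left open for the others. A difference in read number was excluded by thinning the libraries of both arms, without the shallow ones, to 4.84 M reads. This gave 8952 genes against 9175 in the same libraries without thinning, and the ratio to the full count was 1. Thinning does not make libraries alike in other ways. The median number of genes without reads was 957.5 in untreated BMKO at a median of 8.79 M reads. In untreated WT it was 649.5 at 5.76 M. Whether library quality apart from depth adds to the count was not tested.

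Fewer genes were rhythmic in BMKO liver with rapamycin than with vehicle. A wider total spread between libraries was excluded, since the ratio of the median residual SDs was 0.852. Those SDs include sets by replicate number, which were more marked with vehicle (median correlation 0.555 against 0.285). A wider spread apart from the sets was not tested. A single odd replicate was excluded for replicate 1, as the ratio of the counts without it was 0.0058, but without replicate 2 the counts were 0 and 14 and without replicate 3 they were 6 and 12. Lower amplitudes, the biological explanation, met their prediction, as 85.5% of the genes with rhythms shared by both genotypes had a lower amplitude with rapamycin. A rhythm call rests on the amplitude against the spread in these same libraries, so this largely restates the drop. Why the amplitudes were lower, from the drug or from sets of libraries, was not tested.

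Labels of libraries were shuffled 100 times, real labels included, for each count. For rhythmic genes the real count was reached 1 time in every arm except BMKO with rapamycin, where it was reached 3 times and the highest shuffled count was 506. For daily means it was reached 1 time in every comparison except dusk against dawn AZD8055, where it was reached 3 times with up to 1307 genes. For rapamycin in BMKO, however, the highest shuffled count was 1335 against a real 1468. For BMKO against WT it was 4096 against a real 8915. For rhythm differences it was reached 1 time for arrhythmic against night feeding (highest other 576), dawn AZD8055 (1498), dusk against dawn AZD8055 (376) and feeding under tunicamycin (84), 4 times for ad libitum feeding (1524), and 2 times for rapamycin in BMKO (653), for dusk AZD8055 (893) and for dusk AZD8055 with tunicamycin (24). It was reached 12 times for BMKO against WT (4492), 6 times for TSKO (342), and 100 times for rapamycin in WT (143) and for RPKO (1289), where the real count was 0. Arm labels mixed unevenly over times turn a difference in arm means into a rhythm, which inflates these counts. With each arm's mean subtracted first, the count was reached 1 time for BMKO (highest other 4), arrhythmic (78) and ad libitum feeding (57), dawn (47), dusk (7) and dusk against dawn AZD8055 (296) and feeding under tunicamycin (22). It was then reached 2 times for AZD8055 with tunicamycin (5) and for rapamycin in BMKO (1164, against a real 40), 9 times for TSKO (4), and 100 times for rapamycin in WT (417) and RPKO (1). The high shuffled counts thus remained for rapamycin in BMKO and WT, and there may come from sets of libraries by replicate number, which the shuffles ignore (median correlation between times 0.555 and 0.285 in BMKO with vehicle and rapamycin, 0.2 and 0.295 in WT). This was not tested.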

How the results depend on the processing

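The use of edgeR on recovered reads, of pseudocounts 0.1 and 2, of the deposited scaling and of tests without doubted libraries was chosen only after the result was seen. Of 538 values under alternatives other than leaving out a replicate number, 475 stayed the same and 63 moved. Counts were the same within 1.5 times, levels of the targeted genes within the SD, and shares of peaks within a binomial interval. When a replicate number was left out, 49 stayed the same and 93 moved. Over 226 gene results, more than the text names, since genes kept by most alternatives were preferred after these tests, 2312 values kept direction and call, 48 lost the call and 2 reversed. Leaving out a replicate number, which removes 1 in 3 libraries, or 1 in 4 with tunicamycin, left 571 the same, with 130 weaker and 3 reversed. Except where an alternative tests another threshold, fewer libraries or a pooled spread, the cause was not tested.

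A minimum fold of 1.5 lowers counts by construction. Daily means were then 941 for arrhythmic feeding, 1564 for ad libitum feeding, 5596 for BMKO, 644 for vehicle, 657 for rapamycin in WT, 435 in BMKO, 1044 for the difference of these, 935 for TSKO, 1294 for RPKO, 1048 for dawn and 1425 for dusk AZD8055, 53 between these, 28 for feeding and 220 for AZD8055 under tunicamycin.

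With DESeq2 rhythm differences were 174 for ad libitum feeding, 13 for rapamycin in WT, 79 in BMKO, 8 for TSKO, 2 for RPKO and 35 for AZD8055 under tunicamycin, daily means for feeding under tunicamycin 129, and rhythmic genes 1344 in BMKO, 1057 in WT with rapamycin, and 1251 and 225 in BMKO with vehicle and rapamycin. In a joint fit, with a pooled spread, rhythm differences were 199 for arrhythmic and 35 for ad libitum feeding, 904 for BMKO, 17 for rapamycin in WT and 136 in BMKO, 0 for TSKO and 1 for RPKO. Daily means there were 2511 for rapamycin in BMKO, 2920 for its difference from WT and 138 for dusk against dawn AZD8055. Rhythmic genes there were 822 under ad libitum and 523 under arrhythmic feeding, 3216 in BMKO, 1957 in WT with rapamycin, and 1487 and 167 in BMKO with vehicle and rapamycin.

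Without the filter rhythm differences were 23 for rapamycin in BMKO and 2 for TSKO. For TSKO they were 3 with DESeq2 size factors, with edgeR on recovered reads and with the deposited scaling, and 6 with a pseudocount of 2, where RPKO had 1. Without the 3 shallow libraries WT rapamycin had 1 and BMKO 1216 rhythmic genes. Without the 2 ad libitum libraries that feeding had 68 differences, and without the tunicamycin library at ZT 16 AZD8055 had 29. Peaks within 2 h left 264 shared rhythms and 24.4 and 12.4% after dawn and dusk AZD8055. The set rhythmic under night feeding gave 48.2 and 58.1%. With an estimated correlation 19 list tests were called.

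The replicate number as a block moved rhythm differences to 2 for TSKO and 16 for AZD8055 under tunicamycin, and rhythmic genes to 987 in WT with rapamycin, 2524 in BMKO with vehicle and 130 with rapamycin, and changed the call of 0 of 226 gene results. In a comparison the block was an effect per number shared by all arms, which leaves the fitted differences between arms unchanged. It does not model sets within an arm, so the unchanged calls do not show that comparisons withstand such sets. Libraries of different arms with the same number had a median correlation of residuals of -0.0938 to 0.184. The limit for pairing, 0.1, was passed for rapamycin against vehicle in BMKO (0.184), ad libitum against night feeding (0.154) and AZD8055 under tunicamycin (0.129). A weak pairing was left open for these, and the numbers gave none in the other comparisons. Within an arm, libraries of the same number at other times had a median correlation of 0.555 in BMKO with vehicle, 0.325 in night-fed WT, 0.295 in WT and 0.285 in BMKO with rapamycin, 0.255 and 0.222 with dawn and dusk AZD8055, 0.2 in WT with vehicle, 0.198 in RPKO and 0.00135 to 0.11 in the other arms, so in several arms the number marked a set of unknown kind. The daily mean tests ignored such sets, so their SE and p-values may be too small in those arms.

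The difference in amplitude of Nr1d1 for dawn AZD8055 was -0.002 with the older edgeR settings, -0.004 with edgeR on recovered reads, -0.029 without replicate 2 and 0.402 without replicate 3. That of Dbp was 0.243 without replicate 1 and -0.203 without replicate 2, and that of Bhmt2 for AZD8055 under tunicamycin was -0.168 without replicate 1 and 0.002 without replicate 3.

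Leaving out each replicate number gave these lowest and highest counts. Daily means were 3256 to 4952 for arrhythmic feeding, 4782 to 5858 for ad libitum feeding, 7791 to 8515 for BMKO, 2816 to 6894 for vehicle, 1275 to 1766 for rapamycin in WT, 593 to 941 in BMKO, 124 to 1615 for their difference, 3063 to 3511 for TSKO, 3905 to 4531 for RPKO, 3286 to 4391 for dawn and 4464 to 5779 for dusk AZD8055, 4 to 446 between these, 13 to 67 for feeding and 398 to 864 for AZD8055 under tunicamycin. Rhythm differences were 33 to 265, 1 to 25, 81 to 469 for arrhythmic feeding, ad libitum feeding and BMKO, 0 to 4 and 2 to 6 for rapamycin in WT and BMKO, 0 for TSKO and RPKO, 598 to 1121, 109 to 169 and 3325 to 3802 for dawn, dusk and dusk against dawn AZD8055, 150 to 411 for feeding and 1 to 5 for AZD8055 under tunicamycin. Rhythmic genes were 1091 to 1436 under night, 410 to 1529 under ad libitum and 232 to 431 under arrhythmic feeding, 66 to 528 in BMKO, 489 to 1035 and 149 to 730 in WT with vehicle and rapamycin, 12 to 1552 and 0 to 9 in BMKO, 995 to 1517 in Albumin-Cre, 1363 to 1677 in TSKO, 722 to 1307 in RPKO, 780 to 2107 and 933 to 1193 with dawn and dusk AZD8055, and 846 to 1981, 393 to 678 and 1441 to 1955 in the tunicamycin arms. Shared rhythms were 50 to 230, and the shares within 4 h 60.5 to 75% and 7.14 to 30.8%.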

Other observations

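The acute phase transcripts named above were then read in each arm, chosen only after the result was seen, and no test was run across arms. Saa2, whose reads are shared with a close copy, had 7719 and 6422 RPM after dawn and dusk AZD8055, 2823 after dusk AZD8055 with tunicamycin, and 326.2 and 301.1 with tunicamycin alone under night and arrhythmic feeding. Lcn2 had 337.5 and 321.5 RPM after dawn and dusk AZD8055, 132.6 after AZD8055 with tunicamycin, and 1.18 under arrhythmic feeding without injection. Mt2, a metallothionein, had 2713 and 2321 RPM after dawn and dusk AZD8055, and 3435 and 1976 with tunicamycin alone under night and arrhythmic feeding, against 126.6 and 14.02 in the uninjected mice of the same feeding. The tunicamycin libraries were made as a separate set, so these values stand side by side only.

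Clock genes of the arms with an intact clock were used to read a clock time from each library. The median of clock time minus labelled time was 4.05 h after dawn AZD8055, with single libraries from 1.8 to 6.9 h, and 1.6 h after dusk AZD8055, with single libraries from -3.2 to 5.3 h. Arrhythmically fed mice without injection had a median of 1.45 h and night-fed WT mice one of 0.7 h.

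In the RPKO arm 78 genes had at most 2 reads in any library of that arm and at least 3 RPM elsewhere, and 75 of these were unnamed gene models or pseudogenes, which leaves open whether this arm was counted with another annotation. In 2 RPKO libraries the values correlated best with the next time point, replicate 1 at ZT 18 with 0.492 against 0.233 for its own and replicate 2 at ZT 22 with 0.555 against 0.495.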
